A study of Candida albicans with 2 samples.

How the data were processed

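RNA sequencing of 2 cultures of the yeast *Candida albicans* strain DAY185 was analysed, 1 control library and 1 library from cells grown with nepodin. Per the labels' protocols, cells at a starting OD600 of 0.1 grew in 25 ml of potato dextrose broth in 250 ml flasks at 37 °C and 250 rpm for 4 h, without or with 10 µg/ml nepodin. Libraries were made from 1.3 µg of total RNA with a strand-specific kit, per the labels' protocols. TopHat and edgeR are named in the submitters' processing notes, with no version, role or order. The genome build and the read counting are not given in the sources used here.

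The deposited files hold 1 value per gene and library on a log2 scale. The control values are log2(x + 1) of a depth-adjusted read count, as read from the values themselves, and the nepodin values were taken to be on the same scale, which their low values do not show. In the control library, 100% of the 520 low values (above 0 and under 100 after undoing the log2) lay within 0.1 of a whole multiple of 0.998. In the nepodin library the best step was 0.823, and 26.5% of 505 low values were that close to a whole multiple. Whole reads were therefore not recoverable for the nepodin library, and the linear value 2^value − 1 is called a unit here. The 6030 genes summed to 18034926 units in the control and 16979266 in the nepodin library. All 6030 gene names matched protein-coding symbols of the RefSeq assembly ASM18296v3, which was used for names, gene order and coding length only. Of these, 2821 had a gene name and 3209 had a systematic ID alone.

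The log2 ratio is the nepodin value minus the control value as deposited. A gene was kept if it reached 5 units in at least 1 library, which kept 5983 genes and left out 47. With 1 library per group there is no replicate check, so no test of the conditions was made and no p-value is given. Counting intervals are exact Clopper-Pearson 95% intervals of the nepodin share of the rounded units of both libraries, put on the log2 ratio scale. They treat units as reads, are approximate for that reason, and cover counting error only, not differences between cultures. At 100 units in each library the 95% half-width is about 0.40 on the log2 scale, and at 1000 units it is about 0.13.

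The 32 gene lists were fixed before the data were examined. For each list with at least 4 measured members, the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins of equal size. A percentile at or below 2.5 or at or above 97.5 is said to lie outside the central range. By chance about 1.55 of 31 lists would do so if lists were independent random draws. With 5 other seeds for the random lists, 0 of 31 lists changed side. Interval bounds of a list median are order statistics of its members. The mitochondrially encoded list had 0 of its 15 members in the tables used here.

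Genes are named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes with a name that reach the median gene of the library in at least 1 library, a fixed set of 18 hyphal, biofilm and drug-response genes, and up to 4 members per list with the largest absolute log2 ratio. Other genes named were chosen after their values were seen, and the text says so. An item that the rule takes is not reported here.

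Alternatives fixed beforehand were pseudocounts of 0.1 and 10, no filter, a filter of 50 units, a median log2 ratio of 0, equal totals, quantile scaling, thresholds of 1.5-fold and 4-fold, the mean in place of the median, unmatched random lists, and lists without shared or near-identical members. The set of near-identical members was written after the files were seen, from textbook gene families. Removing or correcting the genes of a stretch of chromosome 1 was added after seeing the data. The steps were tested on simulated data for this comparison, with Poisson counts around the control values of 6030 genes. Of 50 genes changed 4-fold upward, 50 were at least 2-fold higher, and of 50 changed 4-fold downward, 49 were at least 2-fold lower. Among unchanged genes, 23 of 5774 were at least 2-fold apart. The simulated libraries had counting error alone and no difference between cultures, so this share is not a false-call rate for the real pair. Of 500 unshifted lists of 25 genes, 6.4% fell outside the central range. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.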

Results

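The data comprised 2 RNA-seq libraries of *C. albicans* DAY185, a laboratory strain, 1 from a control culture and 1 from a culture grown for 4 h with 10 µg/ml nepodin, a naphthalene compound of *Rumex* roots. The series title puts the question as the suppression of hyphae and biofilm by nepodin, so genes of filamentation, adhesion and drug response were among the lists described. The control library held 18034926 units and the nepodin library 16979266, and 5983 of 6030 genes passed the low-value filter. The ratios compare these 2 libraries, and the spread between cultures was not measured. "Higher" and "lower" below mean the nepodin library relative to the control library.

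In the nepodin library 559 genes were at least 2-fold higher and 349 at least 2-fold lower, while 5075 lay within 2-fold. The alternative oxidase gene AOX2 had the highest log2 ratio among named genes that met the level of the naming rule, 6.82 (counting interval 6.63 to 7.03), from 205.6 to 23331 units. Next came IFD6, a gene of the aldo-keto reductase family (5.98), YHB1, the nitric oxide-detoxifying flavohemoglobin (5.67), and the polyamine transporter gene TPO2 (5.61). IFD6 borders the interval of raised values described below. UCF1 (5.08), the heme-uptake genes RBT5 (5.06) and PGA7 (4.26), the small heat shock gene HSP21 (4.61) and ALK8, a cytochrome P450 gene (4.08), were also among the 12 highest. The lowest log2 ratio of this set belonged to HGT10, a glycerol permease gene (-4.94, counting interval -5.11 to -4.78), followed by the cell-surface gene PGA45 (-3.94), HWP1 (-3.53), MDJ2 (-3.17), NUP (-2.88) and the phospholipase gene PLB4.5 (-2.78). ZRT2 (-2.62), GIT1 (-2.39), FET99 (-2.33), GAP4 (-2.23), FTR1 (-2.13) and CHT2 (-2.03) completed the 12 lowest.

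The remaining 3 of the 12 highest, GIG1 (5.50), CHL4 (5.32) and the urea transporter gene DUR3 (4.75), lay among 58 neighbouring genes between IFD6 and LPG20 on chromosome 1. LPG20 was named after its value was seen. In the nepodin library, the lowest of the 37 Crick-strand genes there was at 11861 units and the lowest of the 21 Watson-strand genes at 1849 units. In the control library the lowest values were 189.7 and 67.9 units. Of these 58 genes, 46 were at least 2-fold higher, and without the 58 genes 513 genes were at least 2-fold higher and 349 at least 2-fold lower. Values of genes in this interval are given with this limit.

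**Figure D1:**
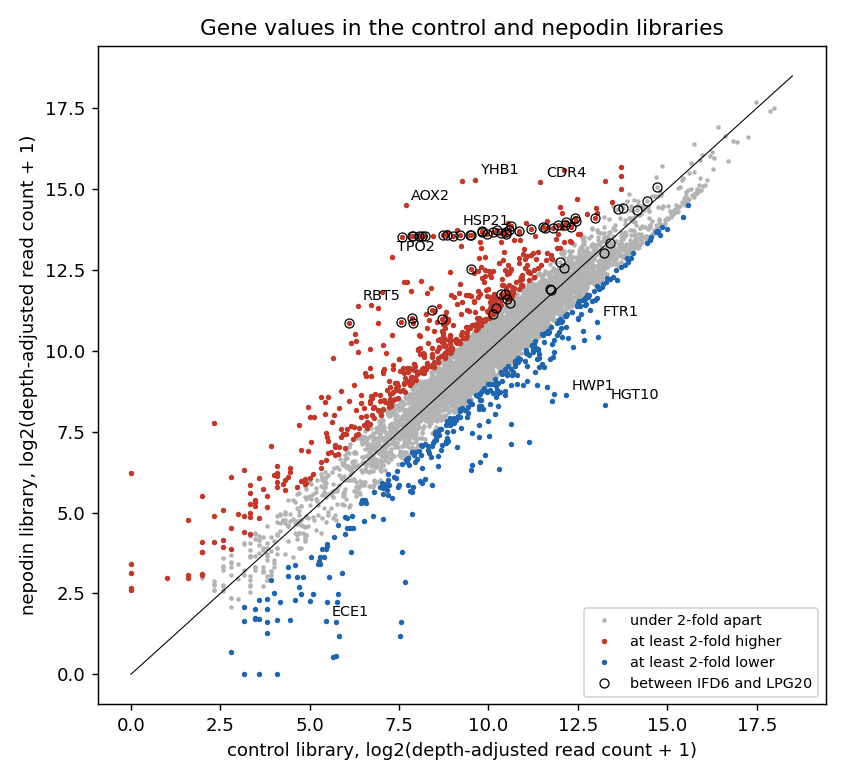
Each point is 1 of 5983 genes, with its value in the control library on the x axis and in the nepodin library on the y axis, both as log2(depth-adjusted read count + 1), and the line marks equal values. Red points are the 559 genes at least 2-fold higher, blue points the 349 at least 2-fold lower, and open circles the 58 genes between IFD6 and LPG20, many of which form a flat row.

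**Figure D2:**
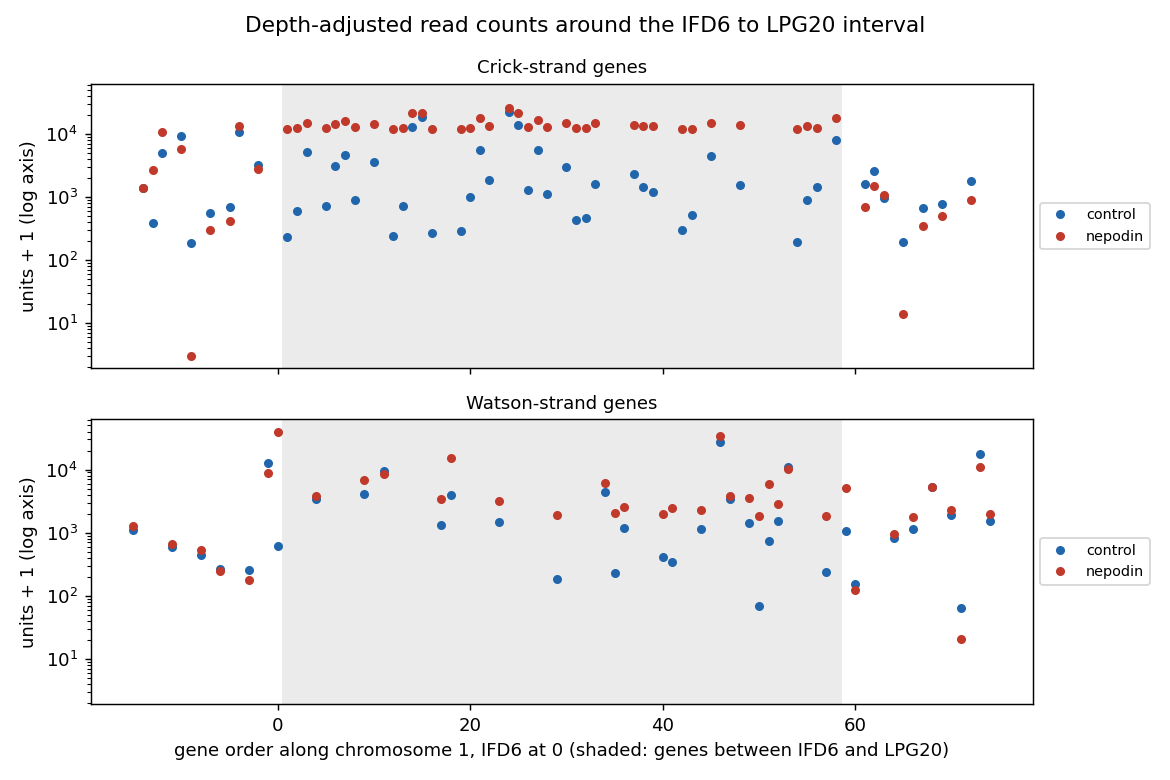
Units plus 1 in the control (blue) and nepodin (red) libraries, on a log axis, against gene order along chromosome 1 counted from IFD6, with Crick-strand genes above and Watson-strand genes below. In the shaded interval the lowest nepodin value of Crick-strand genes is 11861 units, while the control values reach down to 189.7 units.

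Among hypha-induced genes, HWP1, which encodes a hyphal wall adhesin, went from 4588 to 395.5 units (-3.53, counting interval -3.69 to -3.39). ECE1, which encodes the candidalysin precursor, went from 42.9 to 2.14 units (-3.81, counting interval -7.52 to -2.49). SOD5, at 31.0 and 3.77 units (-2.75), and IHD1, at 131.8 and 26.8 units (-2.25), were lower too, as was the filamentation regulator UME6 (-1.10, counting interval -1.58 to -0.66). The median gene of the control library had 1055 units. ECE1, SOD5, IHD1 and UME6 (129.8 units) were thus already low in the control, while HWP1 was above that median. Other members went the other way or differed little: HYR1 was at 1.14 and the hexose transporter gene HGT2 at 2.14, whereas the adhesin genes ALS3 (0.13) and ALS1 (0.33), the cyclin gene HGC1 (-0.20) and the protease gene SAP5 (-0.19) were within 2-fold. Of 21 measured members, 4 were at least 2-fold higher and 7 at least 2-fold lower. The list median of -0.06 was at percentile 25.1 of matched random lists, and it was 0.03 with equal totals, -0.38 as a mean and -1.10 over the 7 members that are in no other list and have no near-identical copy. HWP1, ALS1, ALS3 and SAP5 belong to families of similar genes, so reads between copies can be split wrongly.

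Of 8 yeast-form genes, 6 had a log2 ratio below 0. Their median was -0.72 (order-statistic interval -2.03 to 3.19, 8 members, percentile 0.36), with 2 members at least 2-fold lower and 1 higher, and the mean was -0.32. The yeast wall protein gene YWP1 was at -0.69, the chitinase gene CHT2 at -2.03, PCL2 at -1.15 and RHD3 at -0.83, while RME1 was at 3.19.

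Of 25 activators of filamentation 3 were at least 2-fold higher and 0 lower, with a median of 0.17 at percentile 87.8. RIM101 (1.28), CRZ1 (1.10) and BRG1 (1.07) were the 3 higher members, and TPK2 was at 0.80. EFG1, a regulator of filamentation, was at -0.65, TEC1 at 0.17 and BCR1 at 0.25. Among 8 repressors, with a median of -0.14 (percentile 34.6), RFG1 was at -1.16, NRG1 at -0.20 and TUP1 at 0.23. The 9 biofilm regulators had a median of 0.14 at percentile 77.2, which became -0.0045 with quantile scaling and 0.02 without a wider stretch of chromosome 1 that holds the IFD6 to LPG20 interval, and 1 member was at least 2-fold higher. NDT80 was at -0.62 and GAL4 at 0.55.

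The ALS and other adhesin genes had a median of 0.02 (18 members, percentile 48.1), which was -0.06 with quantile scaling and -0.002 without that wider stretch. It was 0.27 over the 5 members in no other list and without a near-identical copy. Of all 18 members, 3 were at least 2-fold higher, including IFF4 (1.89) and CSH1 (1.12), and 1 was lower, HWP1. The 13 secreted aspartyl protease genes had a median of 0.48 (percentile 93.0), which was 0.14 at percentile 57.7 over the 9 members that pass a filter of 50 units. Of the 13 members, SAP4 was at 1.94 from 9.98 to 41.2 units, SAP9 at 1.51 and SAP1 at 0.99. SAP7 was at -1.63, but it lies in that wider stretch of chromosome 1, where every Watson-strand gene had at least 52.9 units in the control library. CSH1, BRG1 and MRPL37 lie in that stretch too.

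Drug and polyamine transporter genes were higher as a group. Of 19 members, 7 were at least 2-fold higher and 1 lower, and the median of 0.75 (order-statistic interval -0.14 to 1.98) was at percentile 100. Besides TPO2 (5.61), the ABC transporter genes CDR4 (3.76, from 2797 to 37954 units), SNQ2 (3.47) and CDR11 (3.40) had the largest ratios. CDR1 was at 1.98 (counting interval 1.95 to 2.01), CDR2 at 1.86 and MDR1, a major facilitator gene, at 0.75. The quinone and aldehyde detoxification list had a median of 0.70 (order-statistic interval 0.18 to 1.31) at percentile 99.99, with 9 of 23 members at least 2-fold higher and 2 lower. Without the wider stretch of chromosome 1, which holds IFD6, the median of the other 20 members was 0.37 at percentile 98.4. IFD6 (5.98), which borders the interval with raised values, the old yellow enzyme gene OYE22 (4.01), ADH4 (3.52, from 2.99 to 44.9 units) and ADH5 (2.92) led it.

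Oxidative stress genes went both ways. Of 38 members 10 were at least 2-fold higher, among them OYE22 (4.01), the glutathione transferase gene GST3 (2.82) and the superoxide dismutase gene SOD4 (2.25), and 5 were lower, among them SOD5 (-2.75). The median was 0.27 at percentile 98.3, and 0.42 with a filter of 50 units. Of 22 heat shock and chaperone genes, 6 were at least 2-fold higher and 0 lower, with a median of 0.22 at percentile 98.4, which was 88.9 among unmatched random lists, and a mean of 0.57. HSP21 (4.61), HSP104 (2.20), HSP78 (1.77) and HSP70 (1.69) had the largest ratios. The osmotic stress, glycerol and trehalose list had a median of 0.38 (17 members, percentile 99.4), with 3 members at least 2-fold higher and 4 lower. Its percentile was 96.8 among unmatched random lists, and its mean was 0.10. The trehalose synthesis genes TPS1 (1.21) and TPS2 (1.11) were higher, while the glycerol synthesis genes RHR2 (-1.30) and GPD1 (-1.17) were lower.

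Glycolysis and fermentation genes had a median of 0.41 (percentile 99.99), with 5 of 22 members at least 2-fold higher and 0 lower. The mean was 0.63, and the median was 0.17 over the 15 members in no other list and without a near-identical copy. They were led by ADH5 (2.92) and the similar glucokinase genes GLK1 (2.61) and GLK4 (2.61). GPM2 (1.40), counted among the 5, lies between IFD6 and LPG20, and subtracting the lowest value of its strand in that interval left 0.35. The TCA cycle list had a median of 0.32 (order-statistic interval 0.14 to 0.50, 24 members, percentile 99.9, or 96.9 among unmatched lists), where IDP2 (2.04) alone was at least 2-fold higher, and MDH1 (0.72) and KGD2 (0.70) lay within 2-fold. The nuclear-encoded respiratory chain list had a median of 0.09 at percentile 89.7 and a mean of 0.43, and 31 of its 33 members lay within 2-fold. AOX2 (6.82) and the NADH dehydrogenase gene YMX6 (3.53) were the 2 exceptions, and AOX1 was at 0.997 and NDE1 at 0.59. The list for alternative carbon use had a median of 0.37 (34 members, percentile 99.0), with 6 members at least 2-fold higher and 3 lower. The fatty acid oxidation gene POT1-2 was at 2.78 and FRP3 at -1.61. JEN2, a dicarboxylate transporter gene, was at -4.11, from 51.9 to 2.07 units. ICL1, the isocitrate lyase gene, was at 3.17 but lies between IFD6 and LPG20, and subtracting the lowest value of its strand in that interval left 0.51. Hexose transporter genes had a median of -0.01 (18 members, percentile 43.1), which was 0.08 with equal totals, 0.18 at percentile 80.3 with a filter of 50 units and -0.12 at percentile 22.5 with no filter. HGT2 (2.14) and HGT19 (1.98) were higher, and HGT10 (-4.94) and HGT16 (-1.01) lower.

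Genes of iron acquisition split. Of 30 members, 11 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.21 at percentile 2.77. Over the 19 members in no other list and without a near-identical copy the median was 0.18. The direction of the list thus depends on members with near-identical copies or in other lists. The ferric reductase-like gene CFL5 went from 51.9 to 0.49 units, and the iron permease gene FTR2 was at -3.12 and its relative FTR1 at -2.13. The multicopper oxidase gene FET99 was at -2.33. The heme-uptake genes RBT5 (5.06, from 79.8 to 2688 units) and PGA7 (4.26) were higher. In nitrogen and amino acid uptake, 6 of 37 members were at least 2-fold higher and 5 lower, with a median of 0.15 at percentile 78.4. GAP6 (2.70) and the ammonium permease gene MEP1 (2.30) were higher and GAP4 (-2.23) was lower. Both urea genes of the list, DUR3 (4.75) and DUR1,2 (3.03), lie between IFD6 and LPG20. DUR1,2 was still at 2.63 after that subtraction, while DUR3 itself set the lowest Watson-strand value. Gains of the Watson-strand genes there ran from -1211 to 11302 units (median 1661), so 1 subtracted value need not match the excess at each gene. Whether DUR1,2 was raised apart from the interval was therefore not settled.

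Ribosome genes were lower in nearly all cases. All 67 ribosomal protein genes had a log2 ratio below 0, with 11 at least 2-fold lower. Their median was -0.90 (order-statistic interval -0.93 to -0.88, percentile 0). RPL30 was the lowest (-1.38), followed by RPS12 (-1.15), RPL42 (-1.14) and RPL11 (-1.12). Of 61 ribosome biogenesis genes, 60 were below 0 and 10 at least 2-fold lower, with a median of -0.76 (percentile 0). The lowest were MAK16 (-1.36), UTP21 (-1.21), UTP22 (-1.19) and the RNA polymerase I subunit gene RPA34 (-1.18). The 1 member above 0, NOP4 (0.21), named after its value was seen, lies between IFD6 and LPG20. All 16 mitochondrial ribosomal protein genes were below 0 with a median of -0.56 (percentile 0.02), and MRPL37 (-0.98) and MRPL36 (-0.84) were the lowest.

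Ergosterol synthesis genes were lower on the whole. Their median was -0.46 (order-statistic interval -0.79 to -0.21, 24 members, percentile 0.08), with 3 members at least 2-fold lower and 0 higher. ERG2 (-1.12), ERG12 (-1.11) and ERG10 (-1.10) were those 3. ERG11, the target of azole drugs, was at -0.90 (counting interval -0.97 to -0.83) and ERG25 at -0.99. Cell wall genes had a median of -0.09 (50 members, percentile 28.8) and a mean of -0.25, with 9 at least 2-fold lower and 1 higher. PGA31 (-2.57), SCW4 (-2.19, from 13.0 to 2.07 units), CHT2 (-2.03) and PGA5 (-1.47) had the largest ratios.

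**Figure D3:**
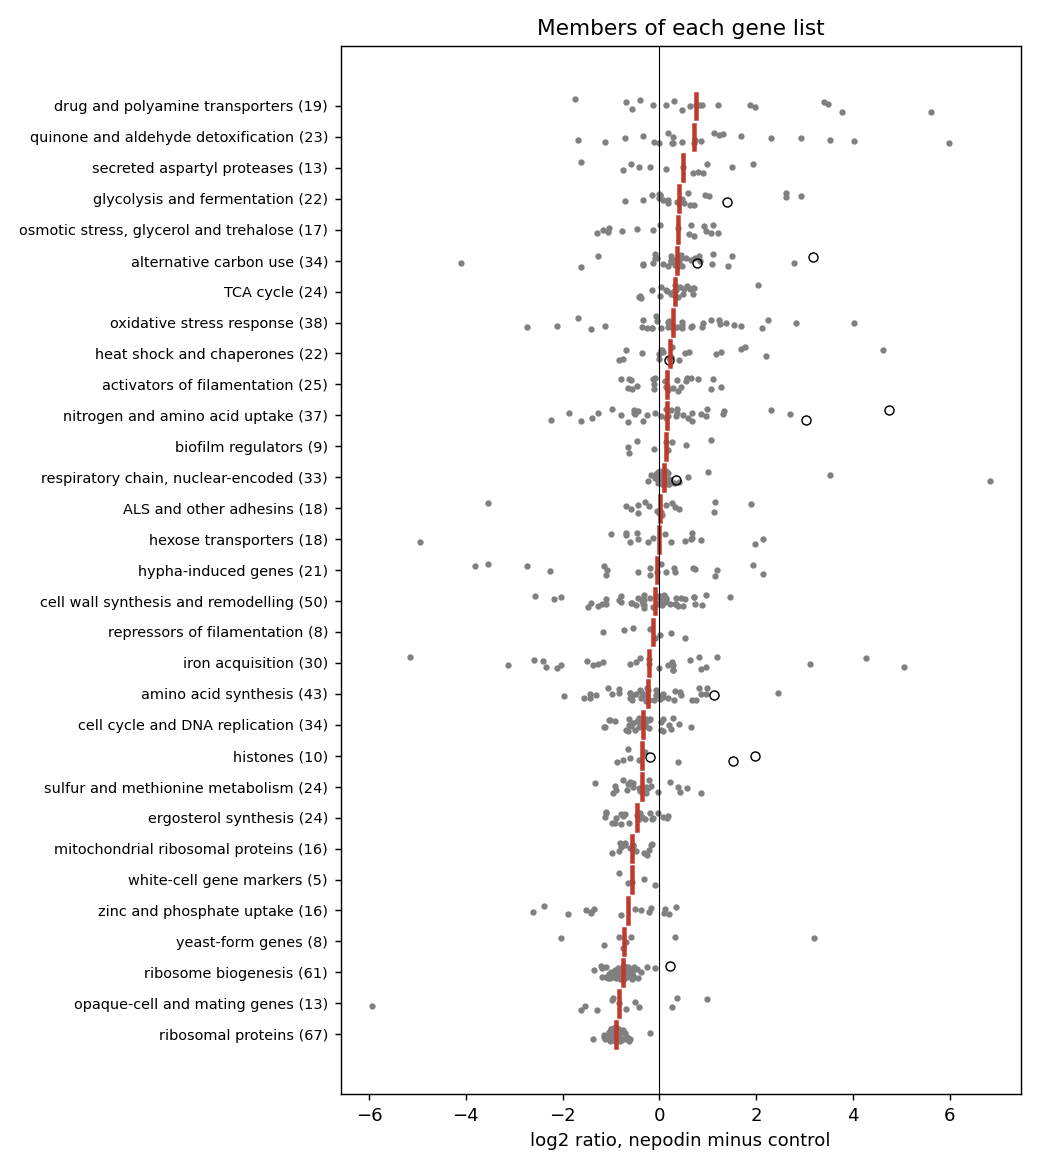
Log2 ratio, nepodin minus control, of every measured member of each gene list, with the number of members in brackets, red bars for list medians and open circles for genes between IFD6 and LPG20. Medians run from -0.90 for ribosomal proteins to 0.75 for drug and polyamine transporters, and positions within a row are spread only so that points do not overlap.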

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

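The settings without, or with correction of, genes of chromosome 1 were chosen after seeing the data. The count of genes at least 2-fold higher (559) became 1177 at 1.5-fold and 175 at 4-fold, and the count at least 2-fold lower (349) became 1053 and 67, by construction of the threshold. Under the other settings the counts stayed within 1.5 times the reported ones, at 499 to 652 and 276 to 423. Of 372 recomputed list medians, 368 lay within their order-statistic interval, which is wide for short lists, and 0 of the medians outside the central range changed sign. The ribosomal protein median was -0.82 with equal totals and -0.64 with quantile scaling, the ribosome biogenesis median was -0.67 with equal totals, and the mean of the respiratory chain list was 0.43, drawn up by AOX2 and YMX6. Of 341 recomputed percentiles, 329 kept their side of the central range. Setting the median log2 ratio to 0 cannot change a percentile. Settings that only filter or remove genes leave the median of a list without those genes as it was. Part of the agreement of medians and percentiles was thus fixed in advance. With unmatched random lists the percentiles were 98.2 for secreted aspartyl proteases, 88.9 for heat shock genes, 96.8 for the osmotic list, 96.9 for the TCA cycle, 1.3 for amino acid synthesis and 0.75 for sulfur metabolism. Iron acquisition was at 2.37 with a pseudocount of 10 and white-cell markers at 2.33 with quantile scaling; the cause was not tested. With the interval background subtracted, amino acid synthesis was at 2.29 and histones at 0.61. Histones were at 1.24 without the genes between IFD6 and LPG20 and at 1.34 without the wider stretch. That subtraction turned the log2 ratios of GIG1 to -0.16, CHL4 to -0.018, HHF1 to -0.61 and HTA2 to -0.81. In the nepodin library GIG1 (11926.5 units) and CHL4 (11967.9 units) lay just above the subtracted 11860.5 units. Their subtracted ratios thus rest on small differences with large counting error. Of 1391 recomputed values of named genes, 1297 lay within the counting interval of the reported ratio. Settings that only filter or remove genes leave a gene's own ratio as it was, so many of these values agree by construction. DESeq2 size factors were not run, since the files hold no counts. No library could be left out and no paired analysis was possible because each group has 1 library. Depth limits the low genes most, such as ECE1 and CFL5.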

Other observations

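Genes of zinc and phosphate uptake were mostly lower, with 7 of 16 members at least 2-fold lower, 0 at least 2-fold higher and 4 above 0. The median was -0.65 (order-statistic interval -1.52 to 0.085, percentile 0.04), and -1.35 over the 13 members that pass a filter of 50 units. The zinc transporter gene ZRT2 was at -2.62, GIT1 at -2.39, PHO100 at -1.89 and GIT3 at -1.52. Amino acid synthesis had a median of -0.24 (43 members, percentile 3.36), with 6 at least 2-fold lower and 2 higher. The arginine pathway genes CPA1 (-1.97) and ARG1 (-1.44) were lower, and the leucine pathway gene LEU1 was at 2.46. The other higher member, LYS21 (1.13), named after its value was seen, lies between IFD6 and LPG20. Sulfur and methionine genes had a median of -0.37 (24 members, percentile 5.76), with CBF1 (-1.32) the 1 member at least 2-fold lower, and MET10 at -0.96 and MUP1 at -0.92.

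Cell cycle and DNA replication genes had a median of -0.34 (34 members, percentile 0.22), with 4 at least 2-fold lower and 0 higher, among them PCL2 (-1.15), NRM1 (-1.12) and PCL1 (-1.05). Histone genes had a median of -0.37 (10 members, percentile 9.51), a mean of 0.0062, and a median of -0.61 over the 7 members outside the IFD6 to LPG20 interval. HHF1 (1.98) and HTA2 (1.52) were the 2 at least 2-fold higher, and both lie between IFD6 and LPG20, while HHF22 was at -0.87 and HHT2 at -0.75. Opaque-cell and mating genes had a median of -0.84 (13 members, percentile 0.14), with WOR3 at -1.30 and MFA1 at -1.62 from 24.0 to 7.11 units. The 5 white-cell markers were all below 0, with a median of -0.56 (percentile 4.05), EFH1 at -0.84, AHR1 at -0.56 and WH11 at -0.31.

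Of the tests in the next 3 paragraphs, those on coding length were set before their values were seen, and the others after.

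Of the 58 genes between IFD6 and LPG20, 46 were at least 2-fold higher in the nepodin library, while some Watson-strand genes, such as HHT21 (-0.20), were not higher; HHT21 and SSA2 were named after their values were seen. A first form of the explanation, that each Crick-strand gene gained a constant number of reads, went against its own bound: the lowest gain, of SSA2, was 23.5% of the median gain of 11627 units. The next lowest, NOP4 (30.1%), APE2 (66.3%) and ACS2 (76.8%), were also named after their values were seen. These genes and SSA2 had 12624 to 22133 units in the control, more than that gain, so lower levels of their own can hide part of it. A second form that allows such changes was written after this outcome. Its value, a lowest nepodin level of the 37 Crick-strand genes 38.1 times the highest such level in equal runs elsewhere, restates the floor that prompted it and so leaves this form open, and the 15 of these genes under 1000 units in the control gained 11459 to 12556 units. A like change in each gene's transcription needs a slope of gain on control level of about 1, and that slope was -0.15 (bootstrap interval -0.25 to -0.04). It was set after the near-constant gain was seen and restates it, so it shows only that gains were not in proportion to the control level. A single long transcript needs a slope of gain on coding length of about 1, if units are not adjusted for length. That slope was -0.10 (-0.29 to 0.02). The near-constant gain already implies a slope near 0, so this shows only that gains were not in proportion to coding length. Reads joined between IFD6 and its relative LPG20 and counted for all genes in between are a candidate source that needs the alignments to test, but both ends are Watson-strand genes while the larger gain is on the Crick strand (median 11627 against 1661 units), which goes against it if counting used strand.

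The mating factor gene MFALPHA was at 187.7 units in the control and 2.06 in the nepodin library (-5.95). It lies in a stretch of chromosome 1 from CAALFM_C103880CA to CAALFM_C105150CA, both named after their values were seen, where no Crick-strand gene of 72 was below 182.7 units in the control. A change of MFALPHA alone was tested on the 6 Crick-strand genes of the stretch under 250 units and outside the IFD6 to LPG20 interval. Of these, 100% were at least 2-fold lower, against 6.07% of 313 genes of 150 to 250 units elsewhere. Without the end genes and MFALPHA this was 3 of 3, so MFALPHA was not the only lower gene there. The stretch was bounded by its control floor, so its low genes were not chosen independently of their control values. The comparison with genes elsewhere therefore cannot decide whether MFALPHA changed for a reason of its own. Reads counted across the stretch in the control cannot be told apart from other causes by the 182.7 floor, because the stretch was bounded by that floor, and no biological explanation was tested.

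Ribosomal protein genes were lower (median -0.90). A lower value of all abundant genes is argued against as the whole cause, since their median differed by -0.63 from that of other genes of the same level (others at -0.27, from -0.49 to -0.10 over draws). Short coding length is argued against in the same way by a difference of -0.70 from genes matched on level and length. With equal totals the median was -0.82. The 2 totals alone fixed the size of that shift, which was 0.087 for the median of all kept genes. It therefore gives the most that unequal totals can account for and is not a test. A response to nepodin may account for the lower values, as a hypothesis, but a difference in growth stage between the 2 cultures stays open, as each condition has 1 library.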
